A study of Mus musculus with 2 samples.

How the data were processed

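CHD2 was precipitated from ES-E14 mouse embryonic stem cells in 2 biological replicates, per the labels. Only peak lists were analysed here. Per the deposited descriptions, the optimal and conservative lists came from the irreproducible discovery rate (IDR) procedure. That procedure scores how well the rank of a peak recurs. Both lists used the relaxed lists of both replicates, the pooled relaxed list and 1 more input of undescribed role. Of the optimal peaks, 304 overlapped a relaxed peak of 1 replicate only and 1 of neither. Not every optimal peak thus recurred between replicates. Each relaxed list came from alignments and 2 files of undescribed role, and ended at 300000 peaks. The mm9 list came from the mm9 alignments of both replicates. The peak caller, its version, the aligner and the filters are not given in the sources used here. The control was not analysed here. How the caller weighed a control, or limited each list, can therefore shift every signal and count.

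The deposited signal value per peak is the caller's own and has no stated normalization. It was used to rank and describe peaks within 1 list. The deposited −log10 q-value was read but entered no test, and the deposited score of the IDR lists, a whole number up to 1000, is not defined in the descriptions and was not used. Summits were taken from the deposited summit offset. Read depth per sample is unknown, and all intervals cover counting error of peaks or genes only. An overlap between peaks was 1 bp or more. To compare replicates, each optimal peak was joined to the strongest overlapping peak in each replicate's own list, and a peak with none was ranked last. The bootstrap interval used 200 resamples of peaks. Replicates' own lists were limited to their 8282 strongest peaks where they replaced the optimal list.

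The mm10 lists were set against RefSeq genes of GRCm38.p6, and the mm9 list against GENCODE M1 and its genome sequence. Coordinates were never moved between builds. The RefSeq table gave gene ends without strand, so the strand was taken from GENCODE M1 by symbol or synonym, which succeeded for 20338 of 21900 protein-coding genes (92.9%). The TSS on mm10 is thus the outer 5′ end of the gene, and internal starts are missed. Promoter CpG was measured over 500 bp on each side of the most 5′ TSS on mm9 and joined to genes by symbol, as a property of the gene. Chromosome length on mm10 was taken as the span of the pooled relaxed peaks. Motif shares had been planned on the optimal list but were measured on the mm9 list, because the genome sequence used here is mm9. A promoter peak had its summit within 1 kb of a TSS, and a distal peak over 10 kb from any.

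The gene lists, the 15 consensus sequences, the tests and most alternatives were fixed before the data were examined. Lists were tested with Fisher's exact test, two-sided, against all other protein-coding genes, with Benjamini-Hochberg adjustment over 25 lists at 0.05. The matched version was a permutation test with 10000 random lists of the same size, drawn within 20 classes of promoter CpG. Each class included the list's own genes. The locus version kept the first gene of each run of members less than 100 kb apart, with Fisher's exact test as before. Motif matches were exact, on either strand, within 50 bp of the summit, against 2 windows centred 500 bp away, with adjustment over the 15 sequences. The split of mm9 summits by exon, intron and space between genes was chosen after the data were seen. Shares carry exact Clopper-Pearson 95% intervals. Differences of medians used permutation tests with 100000 resamples. Genes, peaks and motifs are not biological replicates, so p-values describe these lists and not the spread between cultures.

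The named genes followed a rule. They were the genes at the 15 strongest promoter peaks, the nearest genes of the 5 strongest distal peaks, and per list up to 3 members with the strongest peaks and up to 2 without one. Added were the Chd family with Pou5f1, Sox2 and Nanog, and the 3 promoter peaks with the largest rank difference between replicates. Positions and the signals of each replicate are printed for the first of these groups, the distal peaks, Chd6 and Sox2, in part as ranges. List members are given with the optimal signal alone, to keep the text short. The members without a peak that the rule gives for the developmental and Hox lists are not reported here. Genes beside these, such as Snhg16, Wt1, Gbf1, Eef1b2, Rab6a, H3c7, Zwilch, Rpgrip1 and Tomm40l, were named after their positions were seen, because they lay closer to a named peak. A list symbol was matched through a synonym only where it was not the symbol of another gene. An earlier version had counted H19, a non-coding gene, as Nckap1 in the imprinted list, and this was corrected after the values were seen.

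The list test, the promoter and side counts, the signal ratio, the replicate correlation and the motif shares were tested on simulated data. The CpG difference, the CpG-matched permutation and the X share were not. In 20 draws over 20338 genes, with 5 lists raised from 15% to 45% occupancy, 98 of 100 tests of the raised lists called them higher, and 1 of 360 tests of lists without a change was called. Genes were drawn independently in these draws, so false calls from neighbouring genes that share a peak were not tested. Planted promoter peaks (2000 of 6000) and downstream summits (1200) were all recovered. They had been placed only at TSSs far from any other TSS, so shared promoters were not tested. A planted signal ratio of 2 was found as 1.99, and a sequence planted in 20% of 4000 windows was found in 20.9% of them, with none of the other 14 called. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9.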

Results

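The genome binding of CHD2, a chromodomain helicase of the chromatin remodeller family, was measured by ChIP-seq in ES-E14, a male mouse embryonic stem cell line. There was 1 group of 2 biological replicates, so no treatment or genotype was compared. The optimal list, which was derived from both replicates, held 8282 peaks on mm10 with a median signal of 29.6 and a range of 5.74 to 463. The conservative list held 7530 peaks, of which 5774 were identical to an optimal peak and 6024 overlapped an optimal peak. Each replicate's own relaxed list and the pooled relaxed list held 300000 peaks. A separate list on mm9 held 4613 peaks. Signal is the authors' own value for a peak and was compared only within a list. The number of reads behind each list is unknown, so no precision from depth can be given.

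The strongest CHD2 peaks recurred in both replicates, whereas the overlap was lower over all 8282 strongest peaks. Of the 1000 strongest peaks of replicate 1, 99.4% overlapped one of the 8282 strongest peaks of replicate 2, and 99.7% did so in the other direction. Over all 8282 strongest peaks of each replicate, 4497 peaks of replicate 1 (54.3%) overlapped a peak of replicate 2. The order of promoter peaks was closer between replicates than that of distal peaks, a contrast that was not separated from their higher signal. Spearman's rho between the replicates' signals was 0.739 over 2868 promoter peaks (95% bootstrap interval 0.718 to 0.761) and 0.294 over 3719 peaks more than 10 kb from a protein-coding transcription start site (TSS, 0.261 to 0.325). Over all optimal peaks rho was 0.520 (0.502 to 0.538) and Pearson's r of log2 signal was 0.682 over the 7977 peaks matched in both replicates. Among the 4141 peaks with the weaker optimal signal rho was -0.287. That signal came from both replicates together. Within a narrow range of it, a high value in 1 replicate tends to go with a low value in the other. This rho therefore cannot show how well weak peaks recur. The promoter peaks with the largest rank differences lay at Mgst3, Arrdc2 and Arl6ip1. The Mgst3 peak (signal 19.9, chromosome 1, 167394025 to 167394384) ranked 286849 in replicate 1 and 3709 in replicate 2. The Arrdc2 peak (18.3, chromosome 8, 70839387 to 70839746) ranked 5335 and 287621. The Arl6ip1 peak (19.9, chromosome 7, 118129582 to 118129941) ranked 3631 and 283636. These correlations run across peaks, which are not independent replicates, and carry no p-value.

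CHD2 lay at promoters far more often than random positions did, although 44.9% of its peaks were over 10 kb from a TSS. The highest signal of the list lay at Qrich1 (463, chromosome 9, 108516882 to 108517215), with its summit 71 bp inside the gene. It was followed by Sec23ip, which encodes a partner of the COPII coat (463, chromosome 7, 128744639 to 128744954), and the zinc finger gene Zbtb40 (456, chromosome 4, 137048693 to 137049010). Cdk12, a kinase of RNA polymerase II, had a signal of 436 (chromosome 11, 98202451 to 98202890). Its summit lay 236 bp inside the gene and 39 bp from an end of the long non-coding gene Gm38963. A peak of signal 427 (chromosome 3, 105959132 to 105959532) lay between the divergent genes Atp5pb, an ATP synthase subunit, and Wdr77, a partner of the methyltransferase Prmt5. A peak of signal 423 (chromosome 17, 14943010 to 14943298) was shared by 1600012H06Rik and Wdr27, with its summit 99 bp inside Wdr27. Of 8282 optimal summits, 2868 lay within 1 kb of a protein-coding TSS, which is 34.6% (exact 95% interval 33.6 to 35.7). The share was 1.62% ± 0.146 (SD) over 100 random placements on the same chromosomes, none of which exceeded 2.03%. It was 33.7% with the list of replicate 2 alone and 34.4% with that of replicate 1 alone.

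The other leading promoter peaks lay at the following genes. Hspa4, a chaperone of the Hsp110 family, had a signal of 420 with its summit 4 bp inside the gene (chromosome 11, 53300333 to 53300636). Phf12 had 407 (chromosome 11, 77981675 to 77982012). Atp5b, the catalytic subunit of ATP synthase, had 401 (chromosome 10, 128082997 to 128083305). The proteasome subunit gene Psmb2 had 392 (chromosome 4, 126677460 to 126677738). The translation initiation factor gene Eif5 had 391 (chromosome 12, 111537808 to 111538210) and Tspyl1 had 390 (chromosome 10, 34282009 to 34282290). Between the divergent 5′ ends of Mdh2, the mitochondrial malate dehydrogenase, and Styxl1 lay a peak of signal 386 (chromosome 5, 135778387 to 135778759). Ube2d3, a ubiquitin-conjugating enzyme (chromosome 3, 135438084 to 135438487), and Rpl26, a protein of the large ribosomal subunit (chromosome 11, 68901380 to 68901680), had signals of 385 each. The signals of these 15 peaks in the replicates' own lists ran from 185 at Atp5b to 254 at Qrich1 in replicate 1, and from 172 at Ube2d3 and Mdh2 to 221 at Sec23ip in replicate 2.

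**Figure D1:**
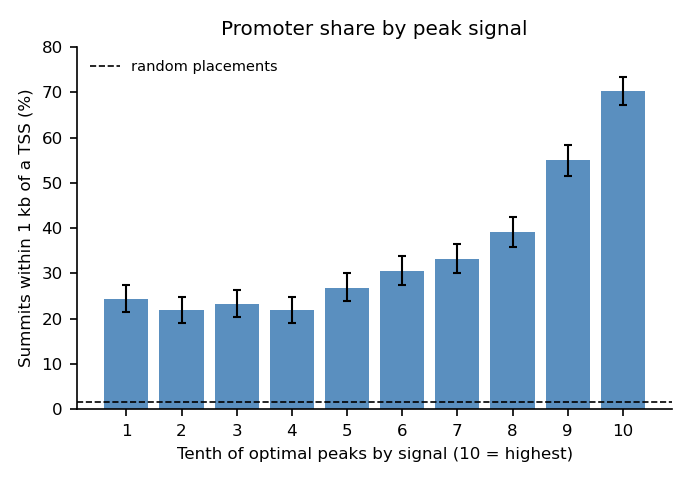
Share of optimal summits within 1 kb of a protein-coding TSS (vertical axis, percent) in 10 equal groups of the 8282 optimal peaks ordered by signal (horizontal axis, 10 is the highest). Bars give the share, error bars the exact 95% interval and the dashed line the mean of 100 random placements (1.62%). The share was 24.4% in the lowest group and 70.3% in the highest.

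Promoter peaks were stronger than distal ones. Median signal was 39.998 over 2868 promoter peaks and 26.7 over 3719 distal peaks, a ratio of 1.496 (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give). Of the 829 peaks with the highest signal, 70.3% lay at promoters (67.1 to 73.4) and 14.4% were distal. Among the 829 with the lowest signal the shares were 24.4% (21.5 to 27.4) and 48.3%. Relaxed pooled peaks below the 8282 strongest lay at promoters in 5.19% of cases. The ratio was 1.57 with the signals of replicate 1 and 1.43 with those of replicate 2.

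The strongest distal peak (signal 405, chromosome 11, 116671429 to 116671765) had Cygb as its nearest protein-coding TSS, with the summit at -17101 bp, but it lay 55 bp from an end of the long non-coding gene Snhg16. The other 4 of the 5 leading distal peaks were weaker. A peak of signal 269 lay inside Arntl, a core gene of the circadian clock, 28807 bp from its TSS (chromosome 7, 113207120 to 113207443). The next, of signal 266 (chromosome 2, 105189433 to 105189683) had Them7 as its nearest TSS, although Wt1 ended closer, at 15945 bp. Zmat3 held a peak of signal 245 (chromosome 3, 32341503 to 32341790). A peak of signal 235 lay at -10259 bp from the TSS of Nfkb2, a subunit of NF-kappaB (chromosome 19, 46290580 to 46290857), and 4225 bp from an end of Gbf1. In the replicates' own lists these 5 peaks had signals from 95.2 at Nfkb2 to 199 at Cygb in replicate 1, and from 97.1 at Zmat3 to 207 at Cygb in replicate 2. On mm9, with exons annotated, 46.0% of 4613 summits lay within 1 kb of a TSS, 1.86% in other exons of protein-coding genes, 19.4% in introns, 1.60% in other genes and 31.2% between genes.

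A promoter peak was found at 2992 of 20338 protein-coding genes, 14.7% (14.2 to 15.2). The list of replicate 1 gave 3078 genes and that of replicate 2 gave 3004, with 2221 in both. Which kinds of gene these were was asked with 25 gene lists, each set against all other genes by Fisher's exact test with Benjamini-Hochberg adjustment over the lists. Occupancy was higher than in other genes for 12 lists and lower for 4. Genes are not replicates, so a call is also given for each replicate's own list where it differs.

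Genes of the ribosome, splicing and protein folding carried CHD2 more often than other genes. Of 78 ribosomal protein genes 33 had a promoter peak (42.3%, against 14.6% of other genes, exact adjusted p = 4.26e-08), with signals of 385 at Rpl26, 380 at Rpl4 and 368 at Rps7. The Rpl4 peak lay slightly nearer to Zwilch. Rpl3 and Rpl5 had none. Of 36 splicing genes 17 had a peak (47.2%, exact adjusted p = 2.20e-05), among them Rbm39 at 324, Hnrnpc at 295 and Srsf10 at 215, while Srsf1 and Srsf9 had none. The Hnrnpc peak lay slightly nearer to Rpgrip1. Of 24 heat shock and chaperone genes 13 had a peak (54.2%, exact adjusted p = 3.10e-05). Its leading members were Hspa4 and the CCT chaperonin genes Cct8 (384) and Cct5 (272), and the inducible Hspa1a and Hspa1b had none. The proteasome list had 10 of 31 (32.3%, exact adjusted p = 0.0281), with Psmb2, Psmb3 at 156 and Psmd3 at 128, and none at Psma1 and Psma2, the latter with a peak in replicate 2's own list. This call was not reached in either replicate's own list, where the difference of 17.6 percentage points became 10.7 in replicate 1 and 14.3 in replicate 2 (exact adjusted p = 0.157 and 0.0560).

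Both lists of mitochondrial genes were also occupied more often, but neither call held against genes of like promoter CpG (permutation test, adjusted p = 0.13 and 0.051). Oxidative phosphorylation had 15 of 41 genes (36.6%, exact adjusted p = 0.00112), with Atp5b, Ndufs1 at 187 and Cox7b at 132. The Ndufs1 peak lay nearer to the TSS of Eef1b2, and Ndufa1 and Ndufa4 had none. Mitochondrial ribosomal proteins had 27 of 78 (34.6%, exact adjusted p = 4.73e-05), with Mrpl57 at 236, Mrps14 at 221 and Mrpl48 at 206, the last nearer to Rab6a. Mrpl1 and Mrpl10 had none.

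Genes that copy, package and remodel chromatin formed a further occupied group. Of 19 genes for histone variants and histone chaperones 11 had a peak (57.9%, exact adjusted p = 5.14e-05). They included Chaf1a, the large subunit of chromatin assembly factor 1 (219), the H3.3 chaperone Hira (164) and Supt16 of the FACT complex (133). The H3.3 genes H3f3a and H3f3b had none, though H3f3a had a peak in replicate 1's own list. DNA replication and repair had 15 of 33 genes (45.5%, exact adjusted p = 6.51e-05), with the helicase subunit gene Mcm3 at 74.5 and a peak of 67.6 inside Prkdc that was counted for Mcm4 as well, and none at Mcm2 and Mcm6, the latter with a peak in replicate 1's own list. Chromatin remodellers had 13 of 35 (37.1%, exact adjusted p = 0.00188), led by Srcap (304), Ino80 (230) and Hells (152). This call ended with a window of 500 bp, where the difference fell from 22.5 to 12.5 percentage points (exact adjusted p = 0.0609), and against genes of like promoter CpG (permutation test, 0.17). The cell cycle list had 10 of 29 (34.5%, exact adjusted p = 0.0113), led by Cdc20 (197), Cdc25c (97.2) and Ccnb1 (87.6), with none at Ccna2 and Ccnd1. The cell cycle call also ended against genes of like promoter CpG (permutation test, adjusted p = 0.28). Replication-dependent histone genes had 27 of 62 (43.5%, exact adjusted p = 3.57e-07). Their leading peak (217) lay between H2ac7 and H2bc7, and a peak of 103 was counted for H2bc9 although H3c7 lay closer. H1f1 and H1f2 had none, though H1f1 had a peak in replicate 2's own list. These 62 genes fall into 5 loci, and with 1 gene per locus the call was not reached (exact adjusted p = 0.219), while the difference moved from 28.9 to 25.4 percentage points. Zinc finger genes named Zfp had 90 of 387 (23.3%, exact adjusted p = 3.10e-05), with Zfp566 at 353, Zfp317 at 328 and Zfp689 at 290, and none at Zfp1 and Zfp105. On the mm9 list the Zfp genes and the heat shock list did not reach the threshold (exact adjusted p = 0.122 and 0.0818).

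**Figure D2:**
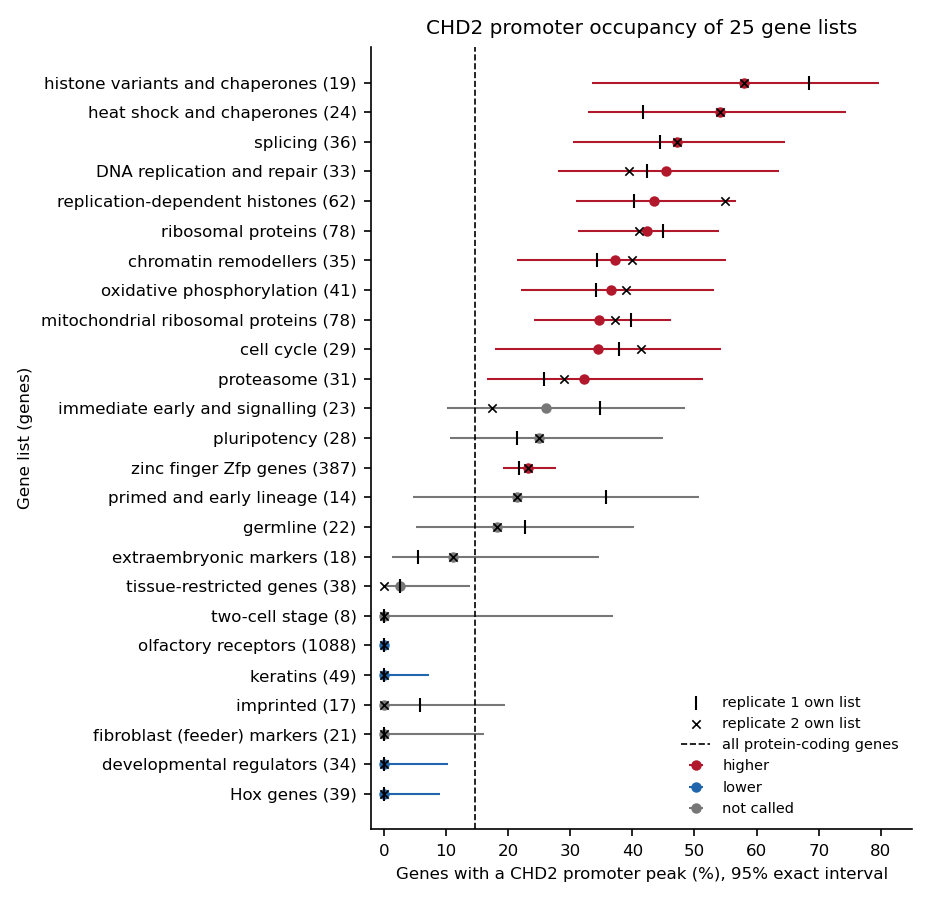
Share of protein-coding genes with a CHD2 promoter peak (horizontal axis, percent) in each of 25 gene lists (vertical axis, number of genes in brackets). Points give the optimal list with exact 95% intervals, coloured by the call of Fisher's exact test, bars and crosses the replicates' own lists, and the dashed line all protein-coding genes (14.7%). The lists called higher lay between 23.3% and 57.9%, and the 4 lists called lower were at 0.

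CHD2 was found at no promoter of 4 lists that were called lower. None of 1088 olfactory receptor genes had a promoter peak (upper 95% limit 0.338%, exact adjusted p = 1.49e-76), Olfr1 and Olfr10 included. None of 49 keratin genes, such as Krt1 and Krt10, had one (upper limit 7.25%, exact adjusted p = 0.00182). Lists of like promoter CpG averaged 1.88% for olfactory receptors and 6.67% for keratins. Against these the olfactory call held and the keratin call ended (permutation test, adjusted p = 0.0025 and 0.13). None of 39 Hox genes (upper limit 9.03%, exact adjusted p = 0.00924) and none of 34 developmental regulators (upper limit 10.3%, adjusted p = 0.0113) had one. Neither was called among the stronger 4141 peaks (exact adjusted p = 0.0553 for Hox and 0.0751 for developmental genes), where both differences were -10.6 percentage points, with no member occupied. On mm9 some member of each list had a peak, and the differences of -8.71 and -8.33 percentage points were not called (exact adjusted p = 0.190 and 0.239). The developmental list and the Hox list have members in common, so their counts are not independent. The Hox genes and the keratins lie in 4 loci each, which are too few for Fisher's exact test to reach the threshold. With 1 gene per locus both differences stayed at -14.7 percentage points, which was fixed in advance because no member was occupied. Among 38 tissue-restricted genes, Apoa2 had the single peak, which lay 36 bp from the TSS of its neighbour Tomm40l (2.63%, exact adjusted p = 0.0526). In the replicates' own lists this group was lower (exact adjusted p = 0.0344 and 0.00754). It was also called lower in the conservative list, the pooled list, at 500 bp, at 2.5 kb and on mm9 (exact adjusted p = 0.0495, 0.0362, 0.0123, 0.0206 and 0.0390). It was not called against genes of like promoter CpG (permutation test, adjusted p = 0.93). Alb and Apoa1 had no peak.

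The pluripotency genes were not called different from other genes within 1 kb. With a window of 2.5 kb the difference rose from 10.3 to 26.1 percentage points and they were called higher (exact adjusted p = 0.00202). Peaks were found at 7 of 28 (25%, exact adjusted p = 0.207), with the highest signals at Klf5 (67.3), Fbxo15 (67.2) and Rif1 (38.5). Pou5f1 and Nanog had none, although Nanog had a peak in replicate 2's own list, and Sox2 had a weak peak (25.8, rank 5045, chromosome 3, 34649891 to 34650250). That peak had a signal of 17.2 (rank 3721) in replicate 1 and 9.11 (rank 13950) in replicate 2. Primed and early lineage genes had 3 of 14, with Etv5 at 49.9, Etv4 at 44.2 and Sox4 at 31.4 (exact adjusted p = 0.509). In replicate 1's own list 5 of the 14 had a peak (35.7% against 15.1% of other genes, exact adjusted p = 0.0670), and in replicate 2's 3 did. Fgf5 and Otx2 had none, though Otx2 had a peak in replicate 1's own list. Germline genes had 4 of 22, led by Tdrkh (105), Sycp1 (100.7) and Tex101 (40.9), with none at Dazl and Ddx4 (exact adjusted p = 0.602). Immediate early and signalling genes had 6 of 23 (exact adjusted p = 0.179), led by Klf10 (74.998), Dusp6 (52.1) and Zfp36 (41.6), and Fos and Fosb had none. This list was called higher in replicate 1 (exact adjusted p = 0.0249) and not in replicate 2 (0.798). It was also called higher in the conservative list (exact adjusted p = 0.0495) and with a window of 2.5 kb, where the difference rose from 11.4 to 35.4 percentage points (exact adjusted p = 2.67e-04). Extraembryonic markers had peaks at Esx1 (99.1) and Tfap2c (23.5) among 18, with none at Sox7 and Gata3 (exact adjusted p = 1). The Tfap2c peak had no match in the list of replicate 1.

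No promoter peak was found at any of 21 fibroblast markers that feeder cells would bring, such as Col1a1 and Col1a2 (upper limit 16.1%, exact adjusted p = 0.0852). The same was true of 17 imprinted genes, Igf2 and Igf2r among them (upper limit 19.5%, exact adjusted p = 0.199), and of 8 genes of the two-cell stage, Zscan4c and Zscan4d among them (upper limit 36.9%, adjusted p = 0.639). Among the imprinted genes Mest had a peak in replicate 1's own list. The imprinted difference was -14.7 percentage points, and -8.27 in the conservative list. None of these 3 lists was called within 1 kb. The fibroblast markers were called lower with a window of 2.5 kb (-16.8 percentage points, exact adjusted p = 0.0465). Within the Chd family, Chd6 carried a promoter peak (131, chromosome 2, 161109035 to 161109233), with its summit at -38 bp. Its signal was 67.5 in replicate 1 and 62.9 in replicate 2. Chd1, Chd2, Chd3, Chd4, Chd5, Chd7, Chd8 and Chd9 had no optimal summit within 1 kb of their outer 5′ end. In the replicates' own lists Chd2 had a promoter peak in both, and Chd9 in replicate 2.

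CHD2 summits lay upstream of the TSS more often than downstream. Of 2865 promoter summits not on the TSS itself, 62.6% were upstream and 37.4% downstream (35.6 to 39.2, exact binomial test, two-sided, p = 1.14e-41). The median position was -37 bp, with quartiles at -115 and 87 bp. The downstream share was 36.7% with the list of replicate 1 and 38.4% with that of replicate 2. With every annotated transcript start on mm9, 76.7% of 2114 summits were upstream and the median was -62 bp.

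Sequence at the summits was read on mm9, over 4613 peaks, since that was the build with a genome sequence. The CCAAT box bound by NFY stood out. It was present within 50 bp of 903 summits (19.6%, 18.4 to 20.7), against 0.921% of the windows 500 bp to each side (Fisher's exact test, odds ratio 26.2). The palindrome TCTCGCGAGA was present at 163 summits (3.53%) and in none of 9225 flanking windows (upper limit 0.0400%, exact adjusted p = 1.85e-78). It lay under the leading peaks at Qrich1, Sec23ip, Zbtb40 and Mdh2. ETS sites were found at 2.10% against 0.184% (exact adjusted p = 1.24e-29), and CRE sites at 0.715% against 0.130% (adjusted p = 1.43e-07). Matches to OCT (1.58% against 0.444%), ESRRB (0.889% against 0.238%), SP/KLF (2.17% against 1.26%), E-box (2.25% against 1.60%), CTCF (0.412% against 0.0542%), ZNF143 (0.282% against 0.0434%) and NRF1 (0.130% against 0.0108%) were also more frequent at summits of all peaks together, with adjusted p between 5.94e-11 and 0.0105. ESRRB was less frequent at promoter summits than in their flanks (0.0471% against 0.330%, exact adjusted p = 0.0378). SP/KLF and E-box were not called at distal summits (exact adjusted p = 1 each), nor CTCF at promoter summits (0.125). ZNF143 and CRE were also not called at distal summits (exact adjusted p = 0.432 and 0.0694), and NRF1 was found at none of 1721. TATAAA was less frequent (2.84% against 5.91%, exact adjusted p = 7.52e-16), but more frequent than in dinucleotide-shuffled summit windows, by 0.694 percentage points (adjusted p = 0.0478). Against windows of promoters without a peak matched on GC, NRF1, SP/KLF, E-box and TATAAA were not called (exact adjusted p = 0.361, 0.241, 0.187 and 0.417). Their differences were 0.0867, 0.412, 0.477 and -0.347 percentage points, over 4613 background windows instead of 9225. YY1 was not called (exact adjusted p = 0.438), but it was higher within 100 bp of the summit (0.499% against 0.130%, adjusted p = 1.26e-04) and against dinucleotide-shuffled windows (0.0425). The long OCT-SOX and RFX sequences were found at no summit (upper limit 0.0799% each). None of the 9225 flanking windows held them either, so their test could show no difference.

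Promoter and distal peaks differed in sequence. The CCAAT box was found at 26.0% of 2123 promoter summits and 13.8% of 1721 distal summits (Fisher's exact test, adjusted p = 3.94e-20). TCTCGCGAGA was found at 7.07% and 0.465% (exact adjusted p = 5.99e-29), ETS at 3.53% and 0.872% (adjusted p = 5.57e-08) and SP/KLF at 4.00% and 0.407% (adjusted p = 1.67e-14). The SP/KLF flanks differed too, with 2.07% and 0.494%, and the odds ratios over the flanks were 1.97 and 0.823. For ETS these odds ratios were 12.9 and 7.56. ESRRB, a site of a pluripotency-linked nuclear receptor, went the other way, with 0.0471% of promoter and 1.80% of distal summits (exact adjusted p = 8.93e-10). OCT matches were found at 0.801% and 2.32% (exact adjusted p = 2.77e-04), but the flanking windows differed too, with 0.306% and 0.755%, and the odds ratios over the flanks were 2.63 and 3.13.

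**Figure D3:**
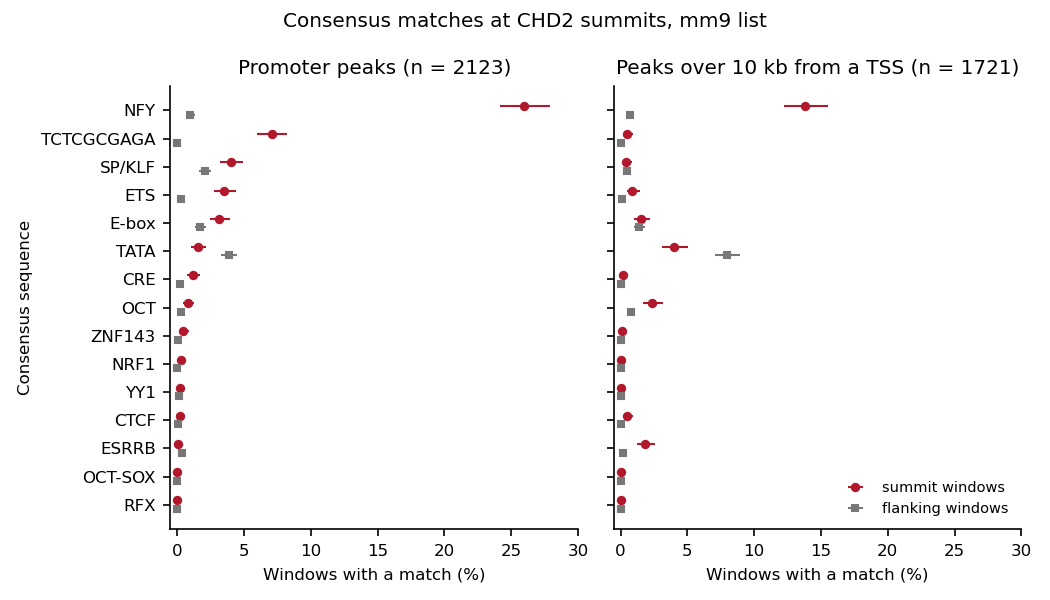
Share of windows with an exact consensus match (horizontal axes, percent) for 15 consensus sequences (vertical axis) at promoter peaks (left) and peaks over 10 kb from a TSS (right) of the mm9 list. Circles are windows within 50 bp of the summit, squares windows of the same width 500 bp to each side, and lines exact 95% intervals. The CCAAT box (NFY) reached 26.0% at promoter and 13.8% at distal summits.

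Promoters with CHD2 were richer in CpG. The median CpG observed/expected ratio was 0.759 over the 2992 genes with a promoter peak and 0.515 over the other 17346 (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give). Of the 4068 genes with the lowest ratio 59 had a peak (1.45%), against 1093 of the 4068 with the highest (26.9%). With list membership permuted among genes of like ratio, 7 of the 12 lists kept their higher call. These were ribosomal proteins, splicing, DNA replication and repair, histone variants and chaperones, heat shock, replication-dependent histones and Zfp genes. Proteasome, oxidative phosphorylation, cell cycle, chromatin remodellers and mitochondrial ribosomal proteins were no longer called (permutation test, adjusted p = 0.43, 0.13, 0.28, 0.17 and 0.051). Their shares were 32.3%, 36.6%, 34.5%, 37.1% and 34.6%, against means of 23.3%, 23.1%, 22.6%, 23.8% and 22.8% in the matched lists. The lower calls held in the same permutation test for developmental regulators and Hox genes (adjusted p = 0.005 each) and for olfactory receptors (adjusted p = 0.0025), and ended for keratins (adjusted p = 0.13). Genes were drawn singly in this test, although the replication-dependent histones and the Hox genes fall into 5 and 4 loci. Matching moved the difference for olfactory receptors from -15.5 to -1.88 percentage points, for ribosomal proteins from 27.7 to 18.2 and for replication-dependent histones from 28.9 to 18.0. The matched lists were drawn from all genes of a CpG class, the list's own included, and not from other genes alone. Part of each shift can come from this, and the olfactory list is the longest, with 1088 genes.

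Few peaks lay on the X chromosome, which this male line holds once. It had 127 of 8261 peaks on the autosomes and X, 1.54% (1.28 to 1.83), against 6.49% of their length and 4.24% of their protein-coding genes (exact binomial tests, two-sided, p = 1.35e-104 and 5.00e-44). The density was 0.744 peaks per Mb on X, and on autosomes it ran from 2.37 on chromosome 14 to 5.67 on chromosome 11. A promoter peak was found at 6.85% of X genes, against 12.3% on chromosome 14, the lowest autosome, and 18.1% on chromosome 11, the highest. Relaxed pooled peaks were also sparse on X, at 22.9 per Mb against 102 to 163 on autosomes. Cox7b (132) and Esx1 carried the X peaks named above. The optimal and pooled relaxed lists held no peak on the Y chromosome, and each replicate's relaxed list held 1. The number of X copies in these cultures was not measured here.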

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

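The alternatives on the mm9 list and the one without the mitochondrial and unplaced sequences were added after seeing the data, and the others were planned. Spearman's rho was 0.629 over the conservative list, 0.407 over the 10000 strongest pooled relaxed peaks, 0.397 with 50% reciprocal overlap and 0.543 with unmatched peaks left out. The cause was not tested. The promoter share ran from 30.3% at 500 bp to 46.0% on mm9 with every transcript start, above all random placements each time, and was 33.7% to 34.4% with 1 replicate left out. Genes with a promoter peak numbered 3004 to 3078 in those runs, and 2347 on mm9. The ratio of promoter to distal signal ran from 1.40 to 1.58, the downstream share of summits from 23.3% to 38.4%, and the share of peaks on X from 1.46% to 1.59%. Their tests held throughout, as did the CpG difference (0.241 to 0.269).

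Lists called higher numbered 10 to 14 except with CpG-matched random lists, which gave 7. Lists called lower numbered 2 instead of 4 with the stronger 4141 peaks, where developmental regulators (exact adjusted p = 0.0751) and Hox genes (0.0553) were no longer called and fewer genes have a peak, and 2 with 1 gene per locus, where 4 loci each remain for keratins and Hox genes. On mm9 the higher calls for heat shock and chaperones (exact adjusted p = 0.0818) and Zfp genes (0.122), and the lower calls for developmental regulators (0.239) and Hox genes (0.190), were not reached. The proteasome call was also lost in the pooled list (exact adjusted p = 0.0700) and the stronger peaks (0.196), and that of chromatin remodellers at 500 bp (0.0609). Pluripotency genes were called higher with a window of 2.5 kb only (exact adjusted p = 0.00202), where immediate early genes were also called higher (2.67e-04) and fibroblast markers lower (0.0465). Motifs called lower numbered 0 instead of 1 with GC-matched promoter windows and 0 with dinucleotide-shuffled windows. TATAAA turned from lower to higher by 0.694 percentage points with the shuffled windows (exact adjusted p = 0.0478), so its direction depends on the background. Tissue-restricted genes were called lower under 7 alternatives (exact adjusted p = 0.00754 to 0.0495). YY1 was called higher within 100 bp (exact adjusted p = 1.26e-04) and against shuffled windows (0.0425). NRF1, SP/KLF and E-box were no longer called with GC-matched windows (exact adjusted p = 0.361, 0.241 and 0.187), nor was NRF1 with shuffled windows (0.144). These backgrounds hold fewer windows, and the NRF1 difference of 0.119 percentage points stayed near its size (0.0867 and 0.108). Among 295 values of single lists and motifs under alternatives, 255 kept their call or lack of one, 25 lost the call, 14 gained one and 1 reversed. Among the 255, the uncalled primed and early lineage list changed sign with CpG-matched lists (6.72 to -0.521 percentage points).

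Motif shares were not run with the conservative list or with single replicates, since those lists are on mm10. The most 5′ TSS was already the setting on mm10, so that alternative was run on mm9 alone (42.9% promoter share). Unknown read depth limits any statement on genes without a peak. No paired analysis was possible because there was 1 group.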

Other observations

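The tests in this part were chosen after the peak lists had been examined. The test of the X chromosome was written after the low share of X had been seen, that of bases picked on odd autosomes after the result for TCGCGA, and the others before their own result was seen. The stretch and TCGCGA were picked from sequences frequent at distal peaks. Site occupancy, the 36 bp windows, the CpG-rich genes of X and the example genes were also chosen after the data were seen. A further test, of optimal peaks with low pooled signal, was drafted and replaced by that of X before it was run. Those peaks numbered 375 past rank 50000 of the pooled relaxed list.

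Divergent promoters carried CHD2 more often than others. Of 1407 genes with another protein-coding 5′ end on the opposite strand within 1 kb upstream, 596 had a promoter peak (42.4%), against 2396 of 18931 other genes (12.7%). The hypothesis that genes with a divergent promoter carry CHD2 more often passed its test (odds ratio 5.07, Fisher's exact test, p = 2.10e-152). A peak between such a pair can count for both genes, so the genes are not independent and the p-value overstates the evidence. The window of a divergent gene also covers the promoter of its neighbour. Pairs were not counted once, and how much these points add to the ratio was not tested. Divergent promoters are also rich in CpG, and within classes of CpG the pooled odds ratio was 3.202.

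Promoter summits with a CCAAT box lay upstream of the TSS in 90.7% of 550 peaks on mm9, with a median of -75 bp. Without the box the share was 71.7% of 1564. The hypothesis that CCAAT summits lie upstream more often passed its test (odds ratio 3.85, Fisher's exact test, p = 5.22e-22). A summit counted here lies within 50 bp of a box, so its side largely follows from where the box lies. The position of CCAAT boxes at promoters without a peak was not measured. The test therefore cannot show how CHD2 itself is placed. CCAAT and TCTCGCGAGA seldom occurred together at promoter summits. Of 149 promoter summits with TCTCGCGAGA 4 also held a CCAAT box (2.68%), against 27.8% of the other promoter summits (odds ratio 0.0717, Fisher's exact test, p = 3.37e-15). Only called summits were compared, and a summit can lie at either sequence without the other. The low odds ratio therefore cannot show that the sequences avoid each other. In 4246 windows flanking promoter summits the CCAAT share was 0.989%, and the 2.68% was not below it. Peaks with TCTCGCGAGA were the stronger, with a median signal of 376 against 64.9 with the CCAAT box and 63.8 with neither. The strongest promoter peaks with a CCAAT box were those at Qrich1, which holds both sequences, Tspyl1, Sp2 and Flad1. Of 179 TCTCGCGAGA sites within 1 kb of a TSS, 154 (86.0%, 80.1 to 90.8) had a summit within 50 bp. The share was 27.6% of 29 sites over 10 kb away, 8.44% of 8184 CCAAT boxes near a TSS and 0.129% of 275709 distal ones.

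Genes of tRNAs lay at CHD2 peaks more often than at randomly placed peaks, and other short RNA genes less clearly. Of 430 tRNA genes 21 lay within 500 bp of an optimal summit, against a mean of 1.23 and at most 5 in 100 random placements. The signal was 184 at n-TRtcg1 on chromosome 13 and 151 at n-TGgcc3 on chromosome 1. It went down to 8.00, at both n-TAagc12 and n-TVaac2 on chromosome 13. Some tRNA genes had the same signal as another on their chromosome, and genes that share a peak were not counted once. Of 390 tRNA genes more than 1 kb from a protein-coding TSS 14 lay at a peak. The counts were 21 of 1228 miRNA genes (at most 12 at random) and 11 of 1004 snRNA genes (at most 9), among them Rnu12 (138), Rnu7 (130) and Rn7sk (47.5). Of the genes at a peak, 7 miRNA and 8 snRNA genes were more than 1 kb from a protein-coding TSS, and neither count exceeds the random maximum for its class. The 7 of 1340 snoRNA genes were within the random range, which reached 11. The genes in this paragraph were chosen after their values were seen.

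A share of the distal peaks lay at copies of 1 interspersed sequence. On mm9, 227 of 1721 distal summits (13.2%) had the stretch ACCCACAGGTTGAGAAC within 50 bp, against 10 of 2123 promoter summits and none of 3442 distal flanking windows (upper limit 0.107%). The leading example lay on chromosome 19, 46365062 to 46365362, between genes and at -14002 bp from the TSS of Nfkb2 (signal 339). Of 105 copies with TCGCGA beside the stretch 81 carried a peak (77.1%), against 233 of 2873 without it (8.11%, odds ratio 38.1, 23.4 to 64.2), but TCGCGA had been picked from peaks of this list. With the bases picked anew on odd autosomes (GGGTCG), copies on the other chromosomes were occupied in 55.8% of 197 cases with them and 4.67% of 1328 without (odds ratio 25.7, 17.3 to 38.4), which argues against reads piling up on all copies alike. Poor read placement on recent copies stays open, because its test could not have come out otherwise: all copies with TCGCGA, occupied (100% of 81) or not, were unique over the 50 bp to each side. Over 36 bp, 96.3% of occupied copies with TCGCGA, 91.1% of all occupied copies and 94.1% of the others were unique. No biological explanation was tested, since there was 1 group.

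The low count on X was weighed against the single copy of X in this line. If signal scaled with copy number, X genes would pass as often as autosomal genes with at least 2 times the lowest signal. Among the 8282 strongest pooled peaks, 7.32% of 861 X genes had a promoter peak (5.67 to 9.26), against 8.26% of 19458 autosomal genes at 2 times the lowest signal and 15.98% at any. Copy number could thus account for the promoter difference at this precision. Distal peaks were not covered by the test. They numbered 43 over 170.68 Mb of X, against 142 over 124.78 Mb of chromosome 14, the autosome with the fewest peaks per Mb. Promoter CpG stays open as a further cause, since its median was 0.410 on X and 0.596 on autosomes, yet among CpG-rich genes 17.0% of 171 on X and 25.1% of 7960 on autosomes had a peak.

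The higher occupancy of housekeeping lists and lower occupancy of developmental lists was weighed against promoter CpG and clustered genes. Of 16 called lists 10 stayed called against CpG-matched lists. Genes were drawn singly, so the replication-dependent histones and Hox genes among them, in 5 and 4 loci, decide nothing on CpG. The developmental list shares members with the Hox list. For the lists of the 10 other than histones and Hox genes, the result argues against CpG as the whole cause. Even so, the difference for olfactory receptors shrank to -1.88 percentage points, against draws that included their own genes. For the 6 lists no longer called, and for the histone and Hox lists, CpG remains open. With 1 gene per locus 13 stayed called. Olfactory receptors fell from 1088 to 84 genes and Zfp genes from 387 to 230, and their calls argue against clustering. The heat shock list fell only from 24 to 22 genes. The rest of the 13 had almost no members within 100 kb of each other. Their outcome was thus nearly fixed, and clustering had little room in them. The 3 lists no longer called were replication-dependent histones, keratins and Hox genes, whose 5, 4 and 4 loci decide nothing. Their differences were 25.4, -14.7 and -14.7 percentage points with 1 gene per locus. The last 2 were fixed in advance, since no keratin or Hox gene had a peak. Expression of these genes was not analysed here, and no biological explanation was tested.

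On mm9 the highest signal of the list, 2854, lay at the end of the mitochondrial sequence (16008 to 16299). The optimal list had 18 peaks on that sequence.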
